A study of Mus musculus with 14 samples.

How the data were processed

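Total RNA from the livers of male mice on a C57/BL6J background was measured on Affymetrix expression arrays. The labels describe 14 samples. At 8 weeks of age 5 control and 5 miR-122 knockout livers were hybridised to an exon array, and at 5 weeks of age 2 control and 2 knockout livers to a gene array. RNA was isolated with the miRVana kit and labelled with biotin using the WT Terminal Labeling Kit, per the labels' protocols. Groups were taken from the genotype labels. The 5-week knockout is labelled as floxed miR-122 with an albumin-driven Cre, which deletes in hepatocytes, whereas the series description calls the 5-week mice germ-line knockouts. The labels do not settle which holds, and the 5-week values are given here as knockout against floxed control. The 8-week control is labelled wild type, and the series description calls the 8-week knockout liver-specific.

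The deposited values are log2 signals per probe set, made by the authors with Affymetrix Expression Console and RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. Versions, annotation and genome build are not given in the sources used here. The 8-week table holds 23332 probe sets and that of 5 weeks holds 35556, rounded to 2 decimals. The authors' deposited table of the 5-week comparison gives log2 group means, a linear fold (ratio of knockout over control) and an unadjusted p-value for 14996 probe sets. Its group means match the sample values within 0.005 log2 units. The test behind its p-values is not given in the sources used here. All rows of that table have a higher group mean of at least 4.94. The 4 per-sample columns of the authors' table were not used, because their names match no sample label.

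Gene names at 5 weeks came from the authors' table and were brought up to date with the RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes. Of the 14996 probe sets, 14908 had 1 symbol and 88 had several, and the latter were left out. Names were matched through the transcript accession for 13056 probe sets, as a current symbol for 987 and as an older symbol for 485. The name in the file was kept for 380. Where a gene had more than 1 probe set, the brightest was used, which left 12871 genes. More than 1 probe set was present for 1048 genes, of which 98 passed the threshold. In 12 of these another probe set had the opposite sign, and in 0 of them did such a probe set pass the limma threshold itself. The files used here do not pair the 8-week probe sets with gene names, so each of the 23332 was tested on its own and gene lists were not tested at 8 weeks. For the same reason the 8-week and 5-week changes were not compared gene by gene. Genes with miR-122 seed sites were not analysed here, since no transcript sequences were used. The miR-122 gene has no named row among the 5-week genes, so its loss was not checked directly.

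Knockout and control were compared within each age with limma (version 3.58.1, lmFit and eBayes, R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The labels give no batch. The series description speaks of 5 control and 5 knockout mice at 8 weeks. At 5 weeks nothing states that the samples came from separate animals, so p-values there measure only the spread between these samples, which can be technical. No 2 samples held identical values. Lists of genes were fixed before the data were examined: 29 lists with 521 entries covering miR-122 targets from earlier studies, metabolism, cell type markers and stress. Each was tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes were chosen by a rule fixed at the same time. It took the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, predicted genes left out, all miR-122 targets of the list, and up to 4 members of each other list with the largest change past the threshold, or the 2 with the smallest p where none passed. Other list members named in the text were chosen after their values were seen. At 8 weeks 4 probe sets are named. The result of 1 gene that the rule names is not reported here. Gene ontology terms in the authors' table with 10 to 300 measured genes were tested with camera after the data were examined.

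The fits were tested on simulated data with the real means, each gene's moderated variance and 200 changed genes. Over 20 simulations of the 8-week comparison on 23332 probe sets, 80.4% of changes of 1 log2 unit and 96.8% of changes of 2 were recovered, and on average 5.21% of the calls were false. For the 5-week comparison on 12871 genes these shares were 98.6%, 100% and 9.99%, so the simulated share of false calls at 5 weeks was above the nominal level. The simulations drew errors independently for each gene and changed only 200 genes. Their shares therefore do not estimate the false calls among the real results. Alternatives covered a filter on genes under the 30th percentile, quantile normalization, centring of arrays on their medians, the mean of all probe sets of a gene, all rows of the 5-week table, a trend and robust prior, array weights, the replicate number as a block, the authors' p-values and leaving out each sample. Array signals carry no depth, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.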

Results

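Liver mRNA of male mice lacking the microRNA miR-122, the most abundant microRNA of hepatocytes, was compared with that of control mice at 8 and 5 weeks of age. The 8-week set held 5 control and 5 knockout livers with 23332 probe sets each, and sample medians lay between 5.37 and 5.42 log2 units. The 5-week set held 2 control and 2 knockout livers, from which 12871 named genes were tested, and sample medians over the whole table lay between 5.92 and 5.96. The arrays were of different types, so values were compared only within an age.

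The 8-week comparison asked which transcripts differ between knockout and control liver in young adult mice. Probe set 6972314 showed the largest rise, from 4.49 ± 0.49 in control to 11.38 ± 0.14 log2 units in knockout livers (SD, n = 5 per group), which is 118-fold (limma adjusted p = 2.02e-07). Probe set 6959254 rose from 3.95 ± 0.31 to 9.38 ± 0.33, or 43.3-fold. Probe set 6922201 fell from 9.98 ± 0.43 to 5.75 ± 0.37, which is 18.7-fold lower, and probe set 6907421 was 9.31-fold lower in knockout livers. These 4 were chosen among probe sets past the threshold in which all 5 knockout samples lay on one side of all 5 control samples. The files used here do not pair these probe sets with genes.

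In total 1037 of the 23332 probe sets passed the limma threshold at 8 weeks, 608 of them higher and 429 lower in knockout livers. The lower count was 238 without knockout replicate 5, 258 without knockout replicate 1, 281 without knockout replicate 2 and 282 without control replicate 4. A change of at least 1.5-fold was present in 485 of them, 306 higher and 179 lower. The groups did not overlap for 1619 probe sets, or 6.94%, where chance gives 0.794% on average over the possible splits. The first principal component held 19.7% of the variance and separated the 5 knockout samples, with scores from 17.37 to 27.52, from the 5 controls, with scores from -32.03 to -16.77.

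**Figure D1:**
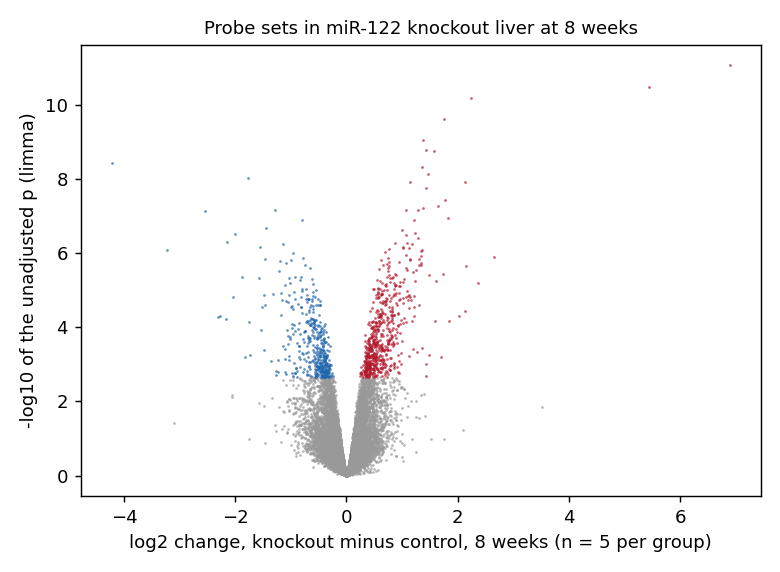
Each point is 1 of the 23332 probe sets at 8 weeks, with the log2 change (knockout minus control) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Red points (608) were higher and blue points (429) lower in knockout livers past the adjusted threshold, and the largest rise was 6.89 log2 units.

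At 5 weeks Igf2, a fetal growth factor, showed the largest rise. It went from 8.64 ± 0.78 to 13.02 ± 0.05 log2 units (SD, n = 2 per group), or 20.7-fold (limma adjusted p = 0.00234). H19, the noncoding RNA beside it, rose 20.5-fold in its brightest probe set and 35.3-fold in a dimmer one. Meg3, another imprinted noncoding RNA, rose 12.1-fold. Afp, the fetal serum protein alpha-fetoprotein, rose 9.71-fold and Spp1, which encodes osteopontin, rose 9.42-fold. Aqp7, a glycerol channel, rose 9.16-fold. Serpina7, Plet1, D17H6S56E-5 and Cib3 made up the rest of the 10 largest rises. Serpina7 differed between the controls, at 4.74 and 7.02, against 9.10 and 9.64 in knockout livers. Its rise was 5.10-fold without control replicate 1 and 24.8-fold without control replicate 2.

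The largest fall was that of Ces3b, a carboxylesterase, which was 29.0-fold lower in knockout than in control livers (limma adjusted p = 0.00213). Hsd3b5, a steroid dehydrogenase of male liver, and Elovl3, a fatty acid elongase, were 21.5-fold and 19.4-fold lower, and both also differed between the controls (9.87 and 6.62 for Hsd3b5, 10.38 and 8.15 for Elovl3). Without control replicate 1 they were 6.96-fold and 8.94-fold lower, and without control replicate 2 they were 66.3-fold and 41.9-fold lower. Cyp2c38 fell by 3.83 log2 units, and Sult2a8 and Slco1a1, an organic anion carrier, were 10.6-fold and 10.3-fold lower. Cyp2c67, Wfdc21, Abhd1 and Cyp4a12a completed the 10 largest falls. Cyp4a12a was at 8.88 and 10.48 in the knockout livers, and it was 2.66-fold lower without knockout replicate 1 and 8.06-fold lower without knockout replicate 2. Ces3b, Sult2a8 and these Cyp genes belong to families of similar sequence, so signal from relatives is not excluded.

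Of the 12871 genes, 1928 passed the limma threshold at 5 weeks, 1394 higher and 534 lower in knockout livers, and 1405 of them changed at least 1.5-fold. The share that was higher was 72.3%, against 61.2% after quantile normalization and 55.9% with arrays centred on their medians. The groups did not overlap for 59.1% of genes, where chance gives 33.3% on average over the possible splits. Genes can vary together, so a single split can lie far from this average by chance. The first principal component held 75.7% of the variance and separated knockout from control samples. Its share therefore includes the tested difference and does not measure how far genes vary together by chance. The count rests on all 4 samples: leaving out any 1 of them gave 0 genes past the limma threshold, with 2267 to 3490 at an unadjusted p under 0.05, and testing all 35556 rows of the table also gave 0, with 5640 at an unadjusted p under 0.05. In simulations of this comparison on 12871 genes, 9.99% of the calls were false on average.

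**Figure D2:**
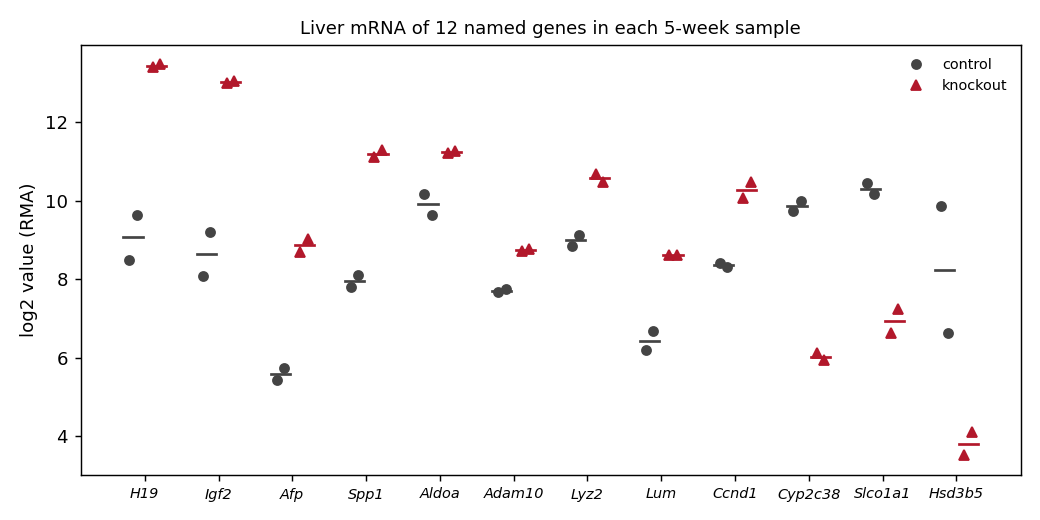
Log2 values (vertical axis) of 12 named genes in each 5-week sample, with circles for the 2 control and triangles for the 2 knockout livers and a bar at each mean. H19 rose from a mean of 9.07 to 13.43, whereas Hsd3b5 was at 9.87 and 6.62 in the controls and at 3.52 and 4.12 in the knockout livers.

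Of the 13 measured oncofetal and imprinted genes, 9 rose and 0 fell, and 10 rose when adjusted over the list alone. Besides the genes above, Rian rose by 2.68 log2 units, Peg3 by 1.92, Grb10 by 1.90 and Gpc3, a cell surface proteoglycan of fetal liver, by 1.54. Dlk1, a marker of fetal hepatoblasts, did not pass (0.14, limma adjusted p = 0.558). The list shifted up in camera (adjusted p = 2.36e-08; adjusted p = 0.405 with an estimated correlation).

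The list of miR-122 targets known from earlier studies had 19 measured members, of which 11 rose and 0 fell, and 14 rose when adjusted over the list alone. All 19 had positive changes, with a median of 0.77 log2 units. Vamp3, a vesicle fusion protein, rose 2.57-fold, Aldoa, a glycolytic aldolase, 2.50-fold, Slc35a4 2.23-fold and Ndrg3 2.15-fold. Adam10, a membrane protease, Bcl9 and Tmed3 rose 2.04-fold, 2.05-fold and 2.03-fold. Gys1, Bckdk, P4ha1 and Ccng1 rose between 1.53-fold and 1.75-fold. Slc7a1, a cationic amino acid transporter, was 1.31-fold higher and did not pass (limma adjusted p = 0.100), nor did Cd320, Hjv, Adam17, Srf, Igf1r, Cux1 and Pkm. The list shifted up in camera (adjusted p = 2.36e-08; adjusted p = 0.405 with an estimated correlation).

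Macrophage and Kupffer cell markers rose in 15 of 19 measured members and fell in 0, and 17 rose when adjusted over the list alone. Cd14 rose 3.16-fold, Lyz2, which encodes lysozyme, 3.02-fold, Mpeg1 2.90-fold and Ctss 2.46-fold. Camera gave an adjusted p of 3.29e-11 (adjusted p = 0.473 with an estimated correlation). Of 13 chemokine and cytokine genes 7 rose, among them Ccl2, a monocyte attractant, at 3.32-fold, and its receptor Ccr2 at 2.62-fold (camera adjusted p = 0.000164; adjusted p = 0.473 with an estimated correlation). Adjusted over the list alone 8 of them rose. The full lists held 21 chemokine and cytokine, 11 neutrophil and 18 lymphocyte genes, and members without a named row were not tested. Tested genes had a mean of at least 4.94 in the higher group, so a gene below this in controls entered only when higher in knockout livers. S100a8 and Ccr2, with control means of 4.78 and 4.785, entered in this way. The shares of members that rose can therefore be too high for the full lists. Of 5 neutrophil markers 4 rose, with S100a8 at 3.69-fold (camera adjusted p = 0.00879; adjusted p = 0.593 with an estimated correlation). Without control replicate 1 or 2 the adjusted p of this list was 0.0521 or 0.102. Of 6 lymphocyte markers only Cd52, which other leukocytes also carry, rose, at 2.92-fold, and the list did not pass (camera adjusted p = 0.13). It passed with genes under the 30th percentile left out (median 0.998 in place of 0.263, adjusted p = 0.031) and without knockout replicate 2 (adjusted p = 0.0116).

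Stellate cell and fibrosis markers rose in 17 of 22 measured members and fell in 0, and 19 rose when adjusted over the list alone. Lum, a matrix proteoglycan, rose 4.52-fold, Klf6, a transcription factor, 3.36-fold, Mmp2, a matrix protease, 2.75-fold and Fbn1 2.38-fold. Acta2 (-0.235 log2 units, SE 0.567), Des (0.095), Lrat (0.505), Reln (0.395) and Col5a2 (0.325) did not pass. Camera gave an adjusted p of 1.86e-10 (adjusted p = 0.405 with an estimated correlation). Progenitor and bile duct markers rose in 9 of 12 members, also when adjusted over the list alone (camera adjusted p = 2.44e-05; adjusted p = 0.587 with an estimated correlation). After Spp1 the largest were Cd24a at 2.76-fold, Krt23 at 2.66-fold and Prom1 at 2.58-fold, and Epcam rose 1.95-fold. The bile duct keratins Krt19 (-0.32 log2 units, SE 0.36) and Krt7 (0.10, SE 0.14) did not pass. The SE of Krt19 exceeded its change, so its direction is not settled. On average the members of this list were 0.43 log2 units higher in control replicate 2 than in control replicate 1. The list median was 0.98 without control replicate 1 and 1.25 without control replicate 2. Endothelial markers had a median of 0.08 log2 units over 12 members: Cdh5 rose 1.37-fold and Lyve1 fell by 0.80 log2 units (camera adjusted p = 0.976).

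**Figure D3:**
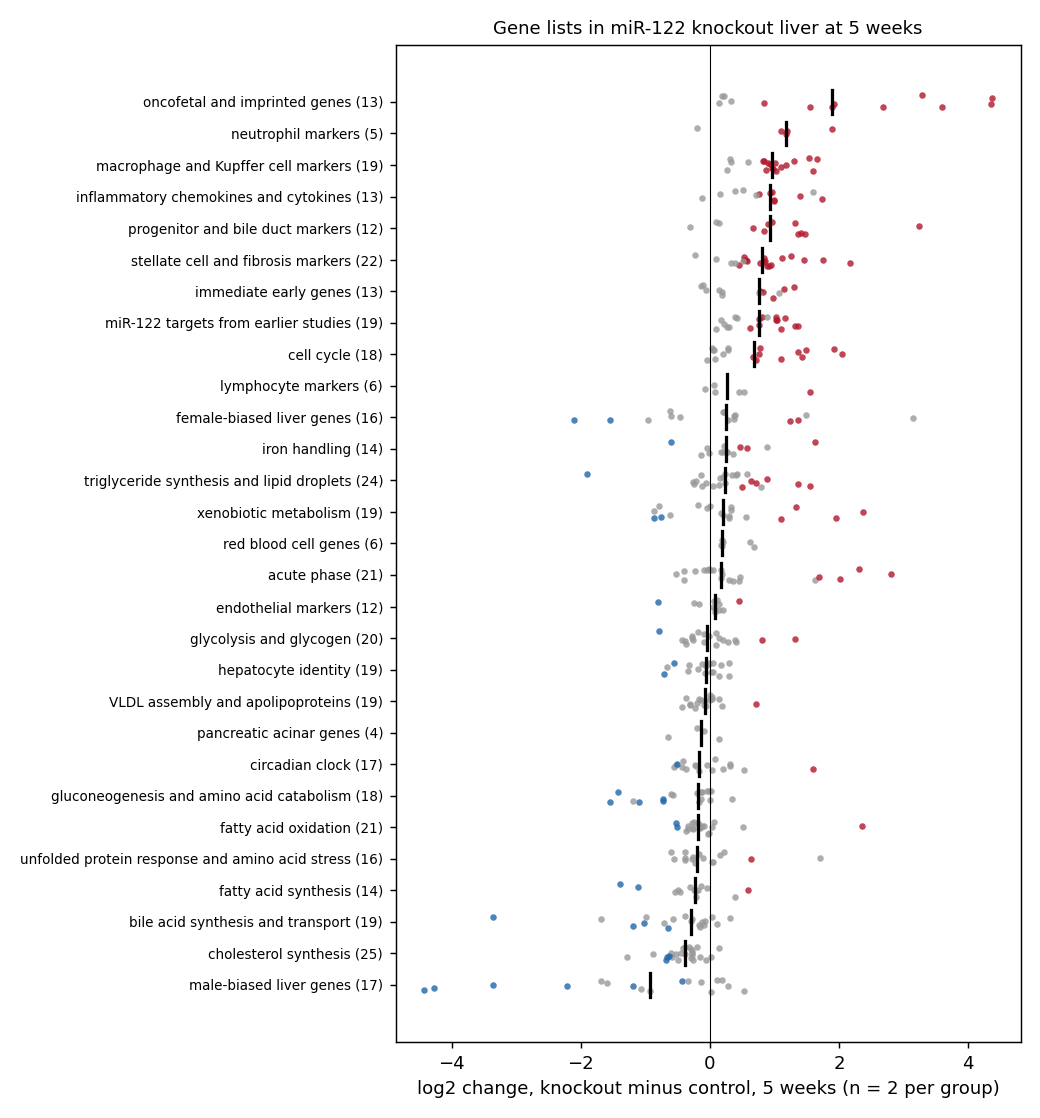
Each point is a measured member of 1 of the 29 gene lists at 5 weeks (number measured in brackets), placed by its log2 change, knockout minus control, on the horizontal axis. Red members rose and blue members fell past the limma threshold, grey members did not pass, and black bars are list medians, from -0.93 for male-biased genes to 1.90 for oncofetal and imprinted genes.

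Cell cycle genes rose in 10 of 18 measured members and fell in 0, and 11 rose when adjusted over the list alone. Ccnb2 and Ccnb1, which encode mitotic cyclins, rose 4.13-fold and 2.82-fold, Ccnd1, cyclin D1, 3.77-fold and Ccna2 2.69-fold (camera adjusted p = 2.56e-05; adjusted p = 0.593 with an estimated correlation). With genes under the 30th percentile left out the list median was 0.17 in place of 0.69 and the adjusted p 0.0623. Of 13 immediate early genes 5 rose, with Jun at 2.47-fold and Nr4a1 at 2.22-fold, and Myc and Ier3 rose 1.96-fold and 1.76-fold (camera adjusted p = 0.0102; adjusted p = 0.593 with an estimated correlation). Without control replicate 1 or knockout replicate 1 the adjusted p of this list was 0.0997 or 0.0635. Of 21 acute phase genes 4 rose: Lcn2 7.01-fold, Saa2 4.94-fold, Saa3 4.06-fold and Orm2 3.22-fold, while the list as a whole did not pass (camera adjusted p = 0.12) except after quantile normalization (adjusted p = 0.0189).

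Male-biased liver genes fell in 6 of 17 measured members and rose in 0, and 9 fell when adjusted over the list alone (camera adjusted p = 0.000314; adjusted p = 0.593 with an estimated correlation). Hsd3b5, Elovl3, Slco1a1 and Cyp4a12a were the largest. Without control replicate 1 the list median was -0.40 and the adjusted p 0.0857. Control replicate 2 lay 1.01 log2 units below control replicate 1 on average over this list. Of 16 female-biased genes Prom1 and A1bg rose, Cyp17a1 and Cyp2c40 fell by 2.11 and 1.54 log2 units, and the list did not pass (camera adjusted p = 0.978).

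Genes of bile acid synthesis and transport fell in 4 of 19 members and rose in 0, and 6 fell when adjusted over the list alone. Besides Slco1a1, Abcg8, a canalicular sterol exporter, fell by 1.18 log2 units, Slc27a5, a bile acid CoA ligase, by 1.01 and Abcc3 by 0.65 (camera adjusted p = 0.000314; adjusted p = 0.473 with an estimated correlation). Of 18 genes of gluconeogenesis and amino acid catabolism 5 fell, and 7 when adjusted over the list alone. Gls2, a glutaminase, fell by 1.56 log2 units, Hal, histidine ammonia-lyase, by 1.42 and Sds, serine dehydratase, by 1.10 (camera adjusted p = 0.000414; adjusted p = 0.593 with an estimated correlation). The urea cycle enzyme gene Otc fell by 0.73.

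Of 24 genes of triglyceride synthesis and lipid droplets 6 rose and 1 fell. Mogat2 and Agpat1, acyltransferases, rose 2.92-fold and 2.58-fold, and Cidec, a lipid droplet protein, 1.85-fold, whereas Lpin1, a phosphatidate phosphatase, fell by 1.90 log2 units (camera adjusted p = 0.0335; adjusted p = 0.593 with an estimated correlation). Without any 1 of control replicates 1 and 2 or knockout replicate 1 the adjusted p of this list was 0.135, 0.0512 or 0.154, and with genes under the 30th percentile left out it was 0.0894. Of 25 cholesterol synthesis genes 3 fell and 0 rose: Ebp, Dhcr7 and Tm7sf2 fell by 0.68, 0.67 and 0.64 log2 units (camera adjusted p = 0.000387; adjusted p = 0.593 with an estimated correlation). This call rests on control replicate 2, in which these genes averaged 1.03 log2 units above control replicate 1. Without it the list median was -0.02 and the adjusted p 0.972.

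Of 14 fatty acid synthesis genes Acss2 and Acacb fell by 1.40 and 1.12 log2 units and Me1 rose 1.51-fold (camera adjusted p = 0.0156; adjusted p = 0.593 with an estimated correlation). The adjusted p of this list was 0.25 without control replicate 2, 0.169 without knockout replicate 1 and 0.0504 with arrays centred on their medians. Of 21 fatty acid oxidation genes Acadvl and Acads fell by 0.53 and 0.52 and Pdk4, a kinase that restrains glucose oxidation, rose 5.10-fold (camera adjusted p = 0.0237; adjusted p = 0.593 with an estimated correlation). The adjusted p of this list was 0.13 without control replicate 2, 0.214 without knockout replicate 2 and 0.223 after quantile normalization. Of 19 apolipoprotein and VLDL assembly genes only Apobec1, the apolipoprotein B mRNA editing enzyme, passed, at 1.65-fold higher (camera adjusted p = 0.133). Of 20 genes of glycolysis and glycogen Aldoa and Gys1 rose and Gys2, the liver glycogen synthase, fell by 0.79 (camera adjusted p = 0.467). The median (-0.05) and the direction of the test were negative for this list and the mean (0.03) positive.

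Hepatocyte identity genes passed in 2 of 19 members, F9 and Foxa2, with changes of -0.71 and -0.55 log2 units. Alb (-0.01) and Hnf4a (0.05) did not pass (camera adjusted p = 0.178 for the list). Of 19 genes of xenobiotic metabolism 4 rose and 2 fell, with Cyp2c55 at 5.19-fold, Gstm3 at 3.85-fold (7.11-fold in a dimmer probe set), Gsta1 at 2.53-fold and Gsta2 at 2.14-fold (camera adjusted p = 0.46). The rise of Cyp2c55 was 8.79-fold without knockout replicate 1 and 3.06-fold without knockout replicate 2. Of 14 genes of iron handling Hmox1, heme oxygenase, rose 3.08-fold, Bmp6 1.49-fold and Slc40a1 1.38-fold, and Tfr2 fell by 0.61 (camera adjusted p = 0.0858). This list passed after quantile normalization (adjusted p = 0.0244) and without control replicate 1 (adjusted p = 0.049). Of 17 circadian clock genes Npas2 rose 3.01-fold (camera adjusted p = 0.19). Atf3 rose 1.55-fold among 16 genes of the unfolded protein response and amino acid stress (camera adjusted p = 0.154). Of 6 red blood cell genes and 4 pancreatic acinar genes 0 passed the limma threshold, and camera gave adjusted p-values of 0.353 and 0.397. Without knockout replicate 1 the red blood cell list had a median of 0.49 in place of 0.19 and passed (adjusted p = 0.00783). At an unadjusted p under 0.05 in limma 0 members of either list passed.

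Adjusted over the list alone, the lists not yet given such a count changed as follows. Among neutrophil markers 4 rose, among lymphocyte markers 2, among immediate early genes 6 and among acute phase genes 5, and 0 fell in each. Endothelial markers had 1 higher and 1 lower, and female-biased genes 2 higher and 3 lower. For triglyceride synthesis and lipid droplets 7 rose and 1 fell, for cholesterol synthesis 0 and 3, and for fatty acid synthesis and fatty acid oxidation 1 and 2 each. Apolipoprotein and VLDL genes had 1 rise, glycolysis and glycogen 3 rises and 2 falls, and hepatocyte identity 2 falls. Genes of xenobiotic metabolism had 4 rises and 3 falls, iron handling 4 and 1, circadian clock 1 and 4, and the unfolded protein response 2 and 2.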

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

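The tests of explanations in this part were chosen after the results were seen.

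At 8 weeks control replicate 4 stood apart from the other 4 controls on the first principal component, with a score of -32.03 against -20.21 for the nearest and -16.77 at the other end. Its gap made up 0.775 of the range, above the limit of 0.71 for 5 samples. It was 1 of 12 groups of values examined, and chance sets off this rule in about 1 in 20. Its score lay on the side away from the knockout samples, and without it 790 probe sets passed the limma threshold in place of 1037. No cause was tested.

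The 8-week count was set against other splits of the same 10 samples. Of 100 splits drawn from the 126 possible, only the real one, 1 in number, gave as many as 1037 probe sets, and the highest of the others gave 2. Chance division of the samples is therefore unlikely to account for that count, though not all of the 126 splits were drawn.

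At 5 weeks the controls differed from each other in genes that distinguish male from female liver. They also differed in genes outside those lists, such as Dmbt1 (5.17 and 10.81), for which no cause was tested. Control replicate 2 was lower than control replicate 1 in 17 of 17 male-biased genes, by 1.01 log2 units on average, and higher in 14 of 16 female-biased genes, by 1.17. A female among the males is argued against by 4 Y-linked genes, whose median in control replicate 2 lay 0.335 log2 units above the mean of the other 3 samples. A knockout liver labelled as control is argued against by the miR-122 target list, on which control replicate 2 lay at -15.4% of the way from control replicate 1 to the knockout mean. A different stage of male maturation stays open as a hypothesis: the mean of -1.01 over the male-biased list is what showed the pattern, so it cannot be told apart from other causes.

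Macrophage, fibrosis and bile duct markers were higher together in knockout livers at 5 weeks. A lower share of hepatocytes alone would raise all other cell types alike, if expression per cell stayed the same. The median change of the 41 macrophage and fibrosis markers exceeded that of 12 endothelial markers by 0.79 log2 units. This gap was more than the SD between the genes of either set (0.479 and 0.308), also without any 1 sample (0.772 to 0.862). It argues against a lower share as the only cause. Among the endothelial markers Cdh5 rose and Lyve1 fell, so their expression per cell may not have been constant. The SD is between genes and not between livers. A lower share together with other changes stays open. More blood left in the knockout livers stays open: the gap of these markers to 6 red blood cell genes was 0.675, but 0.273 without control replicate 1 and 0.382 without knockout replicate 1, within the SD of the markers. For the 12 bile duct markers the gaps of 0.855 and 0.74 lay within their own SD of 0.907, so both explanations stay open for them. A difference in array medians is argued against by centring each array on its median, after which 92.68% of the members that rose still did so. Centring moved the median change of all genes only from 0.005 to -0.08. It therefore could not test a distortion made within the normalization, which stays open. A change in the number of these cells and a change in expression per cell, both with genotype, also stay open and were not tested against each other.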

How the results depend on the processing

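The alternatives below were fixed before the data were examined, except the one restricted to rows at or above the authors' lowest level, which was chosen after seeing the data. At 8 weeks the count of 1037 probe sets stayed within 1.5 times under the filter on dim probe sets (1392), quantile normalization (1339), median centring (1127), a trend and robust prior (1272), array weights (1076) and leaving out each sample (696 to 846). At 5 weeks the count of 1928 genes stayed within 1.5 times under the same filter, normalizations, prior and weights (1461 to 2180), with the mean of all probe sets of a gene (1900) and with the authors' deposited p-values after Benjamini-Hochberg adjustment (1721, of which 1695 were shared). It fell to 0 with all 35556 rows of the table tested and to 822 with the 25740 rows at or above the authors' lowest level; the cause was not tested. Leaving out each sample gave 0 to 0 genes in limma, with 2267 to 3490 at an unadjusted p under 0.05. These fits keep 1 residual degree of freedom and assume that the lone sample varies like the other group. None of the 1928 calls changed sign under any of these settings in which the gene was tested by name.

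The replicate number as a block gave 550 probe sets at 8 weeks, 515 of them shared, and 837 genes at 5 weeks, 822 of them shared. Samples with the same number share only a number: their deviations correlated between -0.0774 and 0.0797 at 8 weeks, where 1 of 5 controls correlated best with its own number, and at 0.043 at 5 weeks. With the block 16 lists passed, as without it.

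Of the 29 lists 16 passed in camera at the preset correlation, 0 with an estimated correlation (lowest adjusted p 0.405), 3 in fry for a common direction (miR-122 targets, oncofetal and imprinted genes, stellate cell and fibrosis markers) and 25 in fry for change in either direction. Leaving out each sample gave 11 to 16 lists. Over the other values, such as single genes and list medians, 1423 of the comparisons with an alternative kept their side of the threshold, 680 lost it, 10 gained it and 0 reversed. Signal over background was not used here. The 8-week alternatives on probe sets per gene, and all alternatives on seed sites and on the comparison of ages, were not run.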

Other observations

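All tests in this part were chosen after results at 5 weeks had been seen, including some of the genes they use.

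Gene ontology terms named in the authors' table were tested at 5 weeks as a wider set of groups, 386 terms in all. In camera 42 shifted up and 13 down, and 0 held with an estimated correlation. Actin cytoskeleton organization rose in 19 of 48 genes and fell in 0 (camera adjusted p = 1.06e-06; adjusted p = 0.702 with an estimated correlation). Antigen presentation by MHC class II rose in 7 of 11 genes, with a median of 1.17 log2 units (camera adjusted p = 0.00132; adjusted p = 0.702 with an estimated correlation). Genes of the electron transport chain fell in 20 of 88 members and rose in 5 (camera adjusted p = 3.74e-06; adjusted p = 0.702 with an estimated correlation). Ribosome biogenesis fell in 3 of 48 genes and rose in 0, with a median of -0.14 (camera adjusted p = 0.00649; adjusted p = 0.702 with an estimated correlation).

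The 5-week controls differed by more than 2 log2 units in 22 genes, against 3 genes between the knockout livers. Cyp2b9, a cytochrome P450 of female liver, was at 5.33 and 12.35 in the controls and at 12.08 and 11.89 in the knockout livers. Dmbt1 was at 5.17 and 10.81 in the controls and at 5.88 and 5.81 in the knockout livers. Muc3 (4.43 and 7.02), Slc26a3 (3.65 and 6.23) and Adgrg7 (4.58 and 6.81) likewise stood out in control replicate 2. In the knockout livers these 3 lay near control replicate 1. Muc1 (5.69 and 7.86) and Acta2 (6.72 and 8.68) were also higher in control replicate 2, with the knockout livers in between. Camk2b went the other way (8.29 and 6.05). The cause of these differences was not tested. All 25 cholesterol synthesis genes were higher in control replicate 2 than in control replicate 1. At 8 weeks 15 probe sets had an SD over 2 log2 units among controls and 21 among knockout samples.

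Since H19, Igf2, Meg3, Rian, Peg3 and Grb10 rose, a hypothesis was that imprinted genes rise as a class. Of 29 other imprinted genes, listed after Phlda2 had been seen to rise, 6 rose and 0 fell, which is 20.7% against 10.8% of all genes. The one-sided Fisher exact p was 0.0866, and the odds ratio of 2.15 had a 95% interval of 0.716 to 5.45, so the data do not decide. Phlda2, Ddc, Igf2r, Sgce, Peg10 and Nnat were the 6.

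A further hypothesis was that sequence beside miR-122 differs between the lines and accounts for changes near it. Among the 20 measured genes nearest to miR-122, 4 of which had been seen beforehand, 3 passed (15%, against 15.0% of all genes), namely Nedd4l, Chmp1b and Tubb6. The one-sided Fisher exact p was 0.594 and the odds ratio of 1 had a 95% interval of 0.188 to 3.47, which leaves the hypothesis open.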
